A study of Mus musculus with 3 samples.

How the data were processed

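The series measured RNA in single cells of sorted mouse prostate epithelium in 3 libraries, 1 per group, and 1 matrix of UMI counts per library was deposited, with its gene and barcode tables. The deposited values are raw counts per gene and cell barcode with no normalization, per the file headers and the values, which are whole numbers. The headers name Cell Ranger 6.1.1 for the wild-type and 6-week libraries and Cell Ranger 7.1.0 for the 10-month library. The submitters' processing notes name Cell Ranger 6.0.0, Seurat 4.2.0 and genome build mm10 for all of them. No header or label says whether reads in introns were counted. The gene tables share 30406 genes, with 647 only in the table of the wild-type and 6-week libraries and 1879 only in that of the 10-month library, and ratios between libraries were computed on genes in both tables. The labels name chip and library kits of different chemistry versions, so the chemistry is not settled. Each library was pooled from at least 3 mice per the labels.

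Barcodes were kept with at least 500 genes and at most 20% mitochondrial UMIs. Scrublet, run through scanpy 1.11.5, called 0, 1 and 0 doublets and so removed next to nothing, which leaves doublets in the data; an alternative removed the cells with the highest scores, 6.42%, 5.72% and 5.62% of each library. The libraries were clustered together without batch integration (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.8 with leidenalg 0.10.2). Clusters were named from marker genes fixed before the data were examined. The scoring that applies them was set after the clusters had been seen: a cluster is basal-like when Krt5 and Krt14 make up more than 0.5 of its Krt5, Krt14, Krt8 and Krt18 level, and luminal-like when they make up at most 0.25. Basal clusters with at least 200.0 CPM of Krt4 were kept apart as Krt4-high, and clusters with a median depth under 0.333 of that of the library giving most of their cells were left unnamed as shallow. Classes outside the epithelium needed a mean log2 ratio of their markers of at least 2 against the other clusters. Epithelial clusters of under 100.0 cells needed a marker of their class among the 10 leading genes.

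Counts were summed per library and class and divided by their total to give CPM. Ratios are log2 of CPM plus 1 over CPM plus 1, and folds are ratios of CPM with exact conditional intervals. Shares carry exact Clopper-Pearson intervals and CPM exact Poisson intervals, at 95%. A fold against a library at 0 UMIs was computed against 3 UMIs in that library and is a lower bound. With 1 library per group no test was made, and list medians are described by their percentile among 10000 random lists of the same size matched on mean expression in 20 bins, with intervals from 1000 Poisson redraws. List members needed at least 10 CPM in either library. The 21 lists, the classes, the contrasts and the rule for naming genes were fixed before the data were examined. The lists are basal identity, luminal identity, androgen-responsive, proximal luminal, NF-kB, immediate early, interferon, MHC class I, MHC class II, innate defence, chemokines, FOXO targets, sterol and fatty acid synthesis, glycolysis, cell cycle, p53 targets, hillock and squamous, mesenchymal, Notch, YAP and TEAD targets, and the PI3K pathway. Some genes stand in several lists, such as Cxcl5 in the NF-kB and chemokine lists. Which lists are described for which comparison was chosen after their values were seen.

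The rule names, per contrast and class, the 6 genes with the highest and the 6 with the lowest ratio among those with at least 100.0 CPM and 50.0 UMIs in the higher library and at least 0.25 of their level in any other class of it. Mitochondrial, ribosomal, haemoglobin, Y-linked and unnamed genes and Xist are left out. It adds up to 2 members per direction of each described list with at least 20.0 CPM, and always Pten, Krt5, Krt14, Trp63, Krt8, Krt18, Ar, Nfkbia, Tnfaip3 and Nfkb1. Intron lengths, overlaps and coordinates come from an mm10 gene annotation, with coordinates counted from 1. For shares of cells with a UMI each cell was thinned to 2000 UMIs and cells with fewer were left out.

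The code for ratios and lists was tested on simulated counts drawn from the real means and depths with 200 genes changed. For basal-like cells at 6 weeks against wild-type (13423 genes) 95.6% of fold intervals held the true value. Of the changed genes 98.0% with a 1.5-fold and 100% with a 2-fold, 4-fold or 8-fold change came out in the right direction. For basal-like cells at 10 months against 6 weeks (11720 genes) 95.4% of intervals held the true value, and for luminal-like cells in the same contrast (13857 genes) 95.4%. Of 100 unchanged lists of 20 genes, 3, 5 and 8 lay beyond percentiles 2.5 and 97.5 in basal-like cells at 6 weeks against wild-type, 10 months against 6 weeks and 10 months against wild-type. In luminal-like cells 3, 3 and 6 did. The simulated genes varied independently of each other and without the intron-length shift of the 10-month library. The check therefore does not calibrate the percentiles of the real lists. The random lists were not matched on intron length, which limits every percentile that involves the 10-month library.

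Alternatives to each choice were fixed before the data were examined: other gene and mitochondrial limits, doublets kept, coarser clusters (resolution 0.4), libraries clustered by themselves, class by the larger keratin set, other thinning and keratin minimums, a smaller keratin set (Krt8 and Krt18 against Krt5 and Krt14), a pseudocount of 10 CPM, TMM factors from edgeR 4.0.16 (R 4.3.3), a total without the 50 top genes, per-cell means, no minimum for members, and proximal or distal cells only. Chosen after the data were seen were the removal of the highest doublet scores, the counting of Krt4-high clusters as basal-like, the naming of shallow clusters by their keratins, the restriction of lists to short introns, the adding of cycling cells by their larger keratin set, and proximal cells as named in each other clustering. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.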

Results

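The data are counts of unique molecular identifiers (UMIs) from 3 droplet single-cell libraries of sorted mouse prostate epithelium, read from the 3' ends of transcripts. Each group has 1 library, pooled from at least 3 mice. The wild-type library holds sorted epithelial cells of CD1 mice. The other libraries hold YFP-positive epithelial cells of mice in which tamoxifen switched on Cre in Krt5-expressing cells, the basal cells of the gland, which deletes Pten and turns on the YFP reporter. They were taken 6 weeks and 10 months after tamoxifen. The series asks what accompanies the passage of basal cells to a luminal state after Pten loss. Its title names innate immunity and the NF-kB pathway. The tables hold 11207 barcodes and 100337204 UMIs (wild-type), 8347 barcodes and 118952076 UMIs (6 weeks), and 7751 barcodes and 145854006 UMIs (10 months). After filtering, 8012, 7149 and 7023 cells were kept, with medians of 8846.5, 12756 and 17059 UMIs per cell. With 1 library per group no difference has a replicate check and none was tested. Intervals are 95% and cover counting error only. Genotype, sort gate and mouse stock differ together between the wild-type and the Pten-deleted libraries. The 10-month table also comes from another software version and gene table. None of these can be told apart from the effect of Pten.

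Pten (ENSMUSG00000013663, chromosome 19, 32757497 to 32826160, mm10) encodes the lipid phosphatase that opposes PI3K signalling. In basal-like cells it was measured at 107 CPM (UMIs scaled to the total of the class; 104 to 109.7) in the wild-type library, at 80.5 CPM (78.1 to 82.9) at 6 weeks and at 59.4 CPM (55.3 to 63.7) at 10 months. In proximal luminal-like cells the values were 115, 77.95 and 61.05 CPM. The labels do not say which exons are removed, and 3' tags can lie outside them, so the Pten level checks neither the deletion nor the labels. YFP was 0 of 94146535 UMIs in the wild-type library, 466.9 CPM at 6 weeks and 140.1 CPM at 10 months. Under the name eGFP the 10-month library gave a further 99.3 CPM, and the 6-week library 0 UMIs. The 10-month library was counted with another gene table, so reporter levels and shares cannot be compared between the times. In cells thinned to 2000 UMIs, a YFP or eGFP UMI was found in 55.3% (53.8 to 56.8) of basal-like and 54.8% (51.8 to 57.9) of luminal-like cells at 6 weeks. At 10 months the shares were 31.0% (28.4 to 33.7) and 37.9% (36.3 to 39.5). Non-epithelial cells, which the Krt5 driver should leave unmarked, had such a UMI in 14.9% (7.66 to 25.04) and 12.6% (6.701 to 21.03), a level that free RNA can give. Of the 6-week luminal-like cells, 58.4% (55.1 to 61.6) of the proximal and 30.6% (22.9 to 39.1) of the distal kind had one. The distal share lies between those of non-epithelial and basal-like cells, so some distal cells may be unmarked. Median depths before thinning were 11673 and 9225 UMIs in basal-like, 28547 and 20403 in luminal-like, and 7176 and 4308 in non-epithelial cells.

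**Figure D1:**
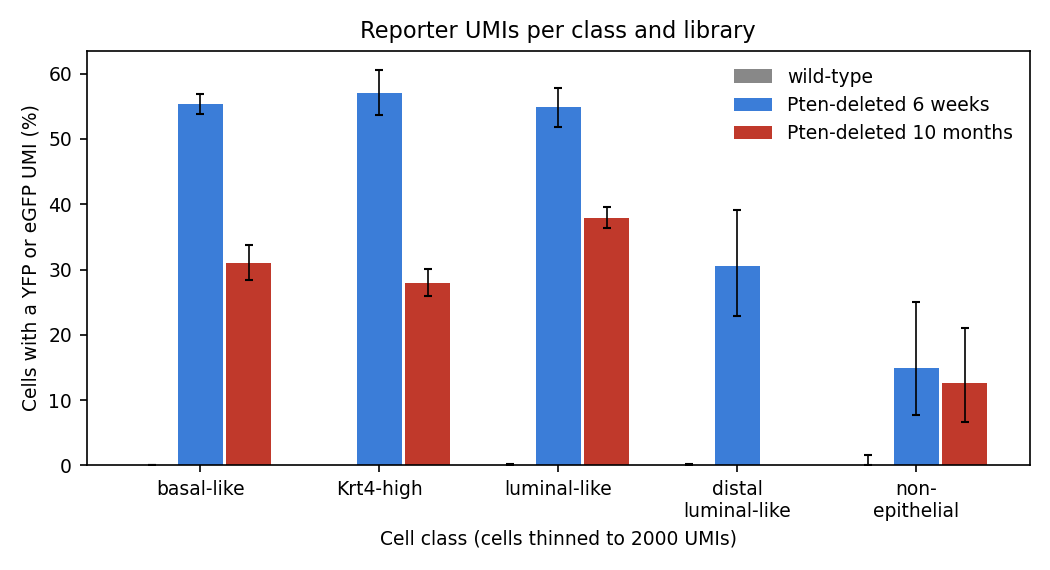
Percent of cells with at least 1 YFP or eGFP UMI after each cell was thinned to 2000 UMIs, by class and library, with exact 95% binomial intervals as whiskers. The wild-type library stands at 0, and the basal-like and luminal-like classes stand above the non-epithelial cells, at 55.3% and 54.8% (6 weeks) and at 31.0% and 37.9% (10 months).

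Luminal-like cells made up 52.0% (50.8 to 53.2) of all kept cells at 10 months and 16.9% (16.02 to 17.8) at 6 weeks, the comparison in which both libraries share a gate. Basal-like cells, whose clusters carry more Krt5 and Krt14 than Krt8 and Krt18, made up 17.9% (17.0 to 18.8) at 10 months and 60.8% (59.6 to 61.9) at 6 weeks. A further group of clusters with basal keratins and Krt4, a keratin of proximal ducts, made up 26.1% (25.05 to 27.1) at 10 months, 11.5% (10.8 to 12.3) at 6 weeks and 0.025% (2 cells) in the wild-type library. The 10 leading genes of its 6-week cluster 3 hold 1 basal marker and 2 markers of another class, and those of its 10-month cluster 20 hold 0 basal markers. The size of this group depends on the clustering: the 1831 and 823 cells at 10 months and 6 weeks become 665 and 174 with each library clustered by itself, and 2991 and 1 with coarser clusters. All 3652 luminal-like cells at 10 months were of the proximal, Krt4-expressing kind, with none of the distal secretory kind (0 of 7023 cells, which allows a share of up to 0.0427%). No marker of the proximal kind was among the 10 leading genes of their clusters 18 and 22. With each library clustered by itself 2615 of the 10-month cells were proximal, 893 luminal without a lobe and 0 distal. At 6 weeks 14.6% (13.8 to 15.5) of cells were proximal and 2.24% (1.91 to 2.61) distal luminal-like, 1047 and 160 cells, against 654 and 327 with the library clustered by itself. In the wild-type library basal-like cells made up 58.9% (57.8 to 60.0) and luminal-like cells 19.9% (19.0 to 20.8), of which 95 cells were proximal and 1497 distal. In a clustering that kept the 1 doublet called, a cell of another library, these were 297 and 799, so the split is unstable.

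A cluster of cycling cells, also left without a class, held 178 cells at 6 weeks, 75 at 10 months and 32 in the wild-type library. Shallow clusters left without a class held 17.5% of wild-type cells, 6.99% at 6 weeks and 0 of 7023 cells at 10 months. That threshold and the Krt4 threshold were both set after the clusters had been seen. The basal-like share at 10 months depended on how cells were grouped: it was 0.114% with coarser clusters, which joined these cells to the Krt4-high ones, and 36.2% when each cell was classed by its larger keratin set.

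**Figure D2:**
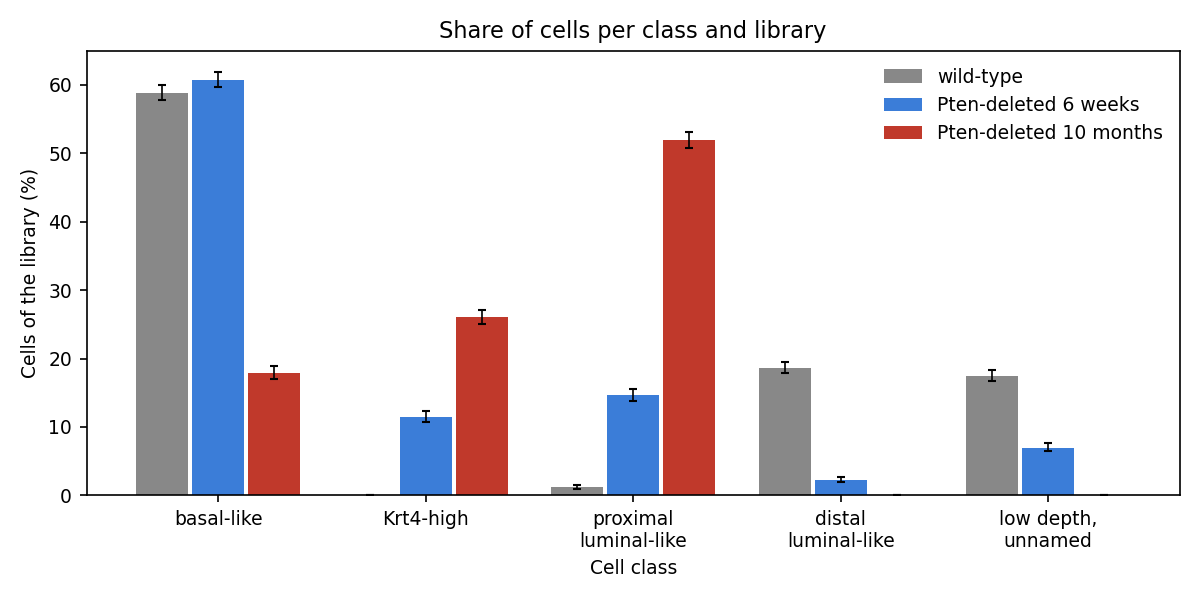
Percent of kept cells in each class, as bars for the 3 libraries, with exact 95% binomial intervals as whiskers. Proximal luminal-like cells stand at 52.0% in the 10-month library against 14.6% at 6 weeks, and basal-like cells at 17.9% against 60.8%.

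Luminal keratins made up a larger part of the keratin UMIs of basal-like cells in the 10-month library than in the others, which includes free RNA. Krt8, Krt18 and Krt19 made up 28.7% (28.4 to 28.9) of their keratin UMIs at 10 months, 14.3% (14.3 to 14.4) at 6 weeks and 23.4% (23.3 to 23.6) in the wild-type library, over the set of these genes with Krt5, Krt14 and Krt15. With Krt15 and Krt19 left out the order was the same, but the 10-month share stood closer to the wild-type one, as listed under the alternatives. In the Krt4-high clusters the share was 23.2% (23.1 to 23.4) at 6 weeks and 34.1% (34.0 to 34.3) at 10 months. Epithelial cells with at least 2 UMIs of each keratin set, after thinning to 2000 UMIs, made up 71.0% (69.9 to 72.1) at 6 weeks, 52.3% (51.1 to 53.5) at 10 months and 54.6% (53.4 to 55.8) in the wild-type library. Within basal-like cells this share was 73.9% at 6 weeks, 72.7% at 10 months and 68.8% in the wild-type library. Within luminal-like cells it was 41.3% at 6 weeks, 33.6% at 10 months and 11.6% in the wild-type library. Of the 1592 wild-type luminal-like cells 1497 were distal, while those at 10 months were all proximal, so the luminal-like shares compare different mixes. Non-epithelial cells, which should lack both sets, gave 27.0% (17.4 to 38.6), 11.6% (5.92 to 19.8) and 8.14% (4.90 to 12.6). Their median depths were 8799, 5226 and 9258 UMIs against 13403.5, 17607 and 9543 in epithelial cells. Free Krt8 RNA was highest at 10 months, at 1614 CPM in macrophages and 783 CPM in fibroblasts, against 407 and 283 CPM at 6 weeks and 315 and 135 CPM in wild-type. Krt19 was highest at 10 months in macrophages (1337 CPM) but at 6 weeks in fibroblasts (605 CPM). Basal-like cells held Krt8 at 859 CPM at 10 months, 574 at 6 weeks and 528 in wild-type, so free Krt8 stands in the same order, and its part in the share was not measured.

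**Figure D3:**
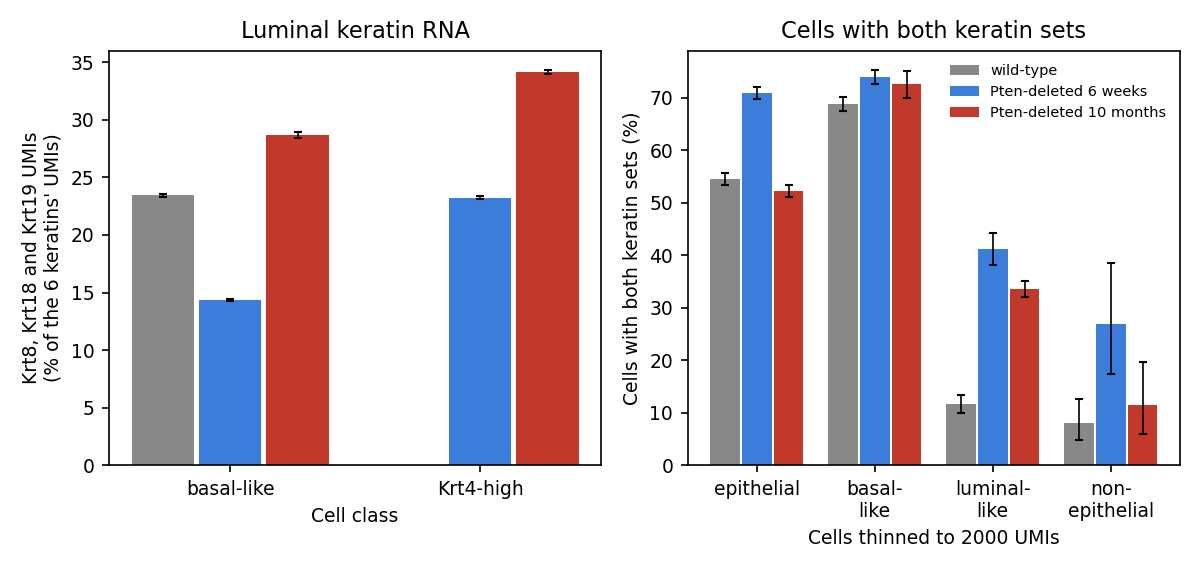
Luminal keratin UMIs as a percent of all keratin UMIs in basal-like and Krt4-high cells (left), and percent of cells holding both keratin sets after thinning to 2000 UMIs (right), as bars per library with exact 95% binomial intervals as whiskers. The luminal keratin share of basal-like cells stands at 14.3% at 6 weeks and 28.7% at 10 months, and non-epithelial cells give the free RNA level of the right panel.

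Basal-like cells at 6 weeks, compared with wild-type, carried higher levels of proximal duct and glycolysis genes. Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031), which encodes the stem cell antigen Sca-1, was 640.1 against 93.5 CPM, 6.85-fold (6.64 to 7.07) higher at 6 weeks, and its relative Ly6d was 14.1-fold (13.3 to 14.8) higher. The proximal luminal list that holds both had a median log2 ratio of 1.66 (1.597 to 1.73), above all 10000 random lists, with 7 of 8 measured members higher, although Krt7 was 3.73-fold (3.56 to 3.91) lower. Proximal luminal-like cells made up 14.6% of the 6-week and 1.19% of the wild-type library. They held Ly6a at 1591 against 73.9 CPM and Ly6d at 817 against 8.57 CPM. Free RNA of these genes was not measured, so its part in the higher basal-like levels stays open. Of the glycolysis genes 14 of 14 were higher, with a median of 0.75 (0.71 to 0.77), above all 10000 random lists, among them the enzyme genes Pgam1 (2.16-fold (2.07 to 2.26)) and Pfkp (1.899-fold (1.78 to 2.03)). The androgen-responsive list stood at -0.86 (-0.96 to -0.77), below all 10000 random lists, with the secreted products Msmb at 38.98 against 614 CPM and Spink1 at 64.4 against 989 CPM. Wild-type fibroblasts, endothelial cells and macrophages held Msmb at 4705, 727 and 417 CPM and Spink1 at 2182, 2159.5 and 14191 CPM. At 6 weeks fibroblasts and macrophages held Msmb at 17.2 and 21.4 CPM and Spink1 at 98.4 and 64.3 CPM. Free RNA thus reaches the Spink1 level of basal-like cells in both libraries, and lies on both sides of their Msmb level in wild-type and below it at 6 weeks. The lower secretory RNA at 6 weeks goes with lower free RNA and cannot be given to the basal-like cells.

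The basal identity list had a median of 0.31 (0.29 to 0.34), at percentile 99.8 of the random lists, led by the basal keratin Krt15 at 8015 against 2828 CPM and by Col17a1, a hemidesmosome collagen, at 252 against 139 CPM, while Lamc2, a laminin chain, was 1.26-fold (1.23 to 1.29) lower. Krt5, Krt14 and Trp63, the p63 gene, were 1.196-fold (1.18 to 1.21), 1.21-fold (1.203 to 1.22) and 1.38-fold (1.34 to 1.43) higher. Krt8 was 1.09-fold (1.07 to 1.105) higher and Krt18 1.24-fold (1.23 to 1.26) lower, and Ar, the androgen receptor gene, was 1.103-fold (1.07 to 1.13) higher. The hillock and squamous list stood at 0.92 (0.804 to 1.05), above all 10000 random lists, with Krt13 8.05-fold (6.86 to 9.501) and Krt16 3.78-fold (3.52 to 4.06) higher and Lgals7 2.19-fold (2.15 to 2.23) lower.

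Among the immune lists the NF-kB list had a median of -0.12 (-0.14 to -0.0946), at percentile 4.51 of the random lists, with 7 of 18 members higher. The feedback inhibitors Nfkbia and Tnfaip3 were 1.04-fold (1.02 to 1.05) and 1.15-fold (1.09 to 1.22) lower. Nfkb1 was 1.13-fold (1.10 to 1.16) lower, the apoptosis inhibitor gene Birc3 1.56-fold (1.48 to 1.65) lower and the chemokine gene Cxcl2 1.33-fold (1.27 to 1.38) higher. The interferon list stood at 0.18 (0.11 to 0.26), at percentile 86.6 of the random lists, with Isg15 2.35-fold (2.11 to 2.61) higher and Ifit2 1.94-fold (1.77 to 2.13) lower, and at 1.15 once the Krt4-high clusters were counted as basal-like. In the other alternatives it ran from 0.0682 without the highest doublet scores to 0.61 with coarser clusters. The chemokine list stood at 0.33 (0.2003 to 0.42), at percentile 95.95 of the random lists, but at -0.0209 without the minimum level for members, and the innate defence list at -0.0693 (-0.17 to 0.0484), at percentile 20.5 of the random lists, with 2 of 7 members at least 2-fold higher and 2 at least 2-fold lower. The MHC class I list stood at 0.22 (0.15 to 0.29), at percentile 93.9 of the random lists, with the immunoproteasome gene Psmb8 1.72-fold (1.58 to 1.86) higher. The FOXO target list, genes held down by PI3K signalling, stood at -0.21 (-0.27 to -0.16), at percentile 0.490 of the random lists, with Insr 1.52-fold (1.39 to 1.68) lower and Txnip 1.78-fold (1.72 to 1.84) higher. The PI3K pathway list stood at 0.15 (0.0408 to 0.27), at percentile 76.8 of the random lists, with Pik3r1, a regulatory subunit gene, 1.49-fold (1.44 to 1.53) higher and Pten 1.33-fold (1.27 to 1.38) lower.

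Among genes within the limits of the naming rule, the highest ratios were those of YFP (at least 7468-fold against the limit of 0 UMIs), the cytochrome gene Cyp2f2 (92.6-fold (83.5 to 103)), Igfbp7 (9.09-fold (8.47 to 9.77)), Ly6a, the glutathione transferase gene Gsto1 (5.77-fold (5.58 to 5.97)) and Ly6e (5.15-fold (5.04 to 5.27)). The lowest were those of Grp, the gastrin-releasing peptide gene (5.004-fold (4.77 to 5.25) lower), Spon2 (3.84-fold), Krt7, the lipopolysaccharide-binding protein gene Lbp (3.59-fold), the ubiquitin gene Ubc (2.84-fold) and the cyclin gene Ccnd1 (2.68-fold). The median log2 ratio of all genes was 0.0481. The wild-type cells lay mainly in clusters 1 and 11 and the 6-week cells in clusters 2 and 4, so the libraries did not mix within the class.

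Basal-like cells at 10 months, compared with 6 weeks, carried higher levels of interferon and antigen presentation genes. The interferon list had a median log2 ratio of 1.91 (1.79 to 1.98), above all 10000 random lists, with 18 of 21 measured members higher, led by Ifi27l2a at 97.7 against 8.89 CPM (10.99-fold (9.89 to 12.2)) and the nucleic acid sensor gene Zbp1 (10.5-fold (8.64 to 12.9)). Irf1 and Cxcl10 went the other way, 2.34-fold (2.11 to 2.59) and 3.24-fold (3.03 to 3.46) lower. Of the MHC class I genes 11 of 11 were higher, with a median of 1.14 (1.096 to 1.199), at percentile 99.5 of the random lists, among them Psmb8 (4.03-fold (3.77 to 4.305)) and H2-Q4 (2.45-fold (2.22 to 2.69)), a member of a family of similar genes and therefore uncertain. The 3 measured MHC class II genes were Cd74 at 125 against 8.66 CPM, H2-Ab1 at 53.4 against 2.73 CPM and H2-Aa at 26.4 against 2.49 CPM, with a median of 3.703 (3.56 to 3.82), at percentile 99.8 of the random lists. Of the 10-month cells 99.7% lay in cluster 17, and of the 6-week cells 66.6% in cluster 2 and 30.98% in cluster 4, so the class sits in different clusters at these times.

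The innate defence list stood at 1.51 (1.32 to 1.598), at percentile 99.95 of the random lists, with the protease inhibitor gene Slpi 117-fold (94.4 to 145) and the antimicrobial lectin gene Reg3g 29.04-fold (25.1 to 33.8) higher, and Il33 2.28-fold (2.16 to 2.41) and Lbp 2.08-fold (1.93 to 2.25) lower. The NF-kB list stood at 0.68 (0.5995 to 0.73), at percentile 98.9 of the random lists, with the neutrophil chemokine gene Cxcl5 (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624) at 48.1 against 1.78 CPM, 27.1-fold (21.8 to 33.9) higher. Free RNA reaches that level, as fibroblasts of the 10-month library held Cxcl5 at 48.7 CPM (26.6 to 81.7). They held Reg3g at 66.1 and Slpi at 31.3 CPM, and macrophages Slpi at 166 CPM, against 110.3 and 196 CPM in basal-like cells for Reg3g and Slpi. Nfkb1 was 3.16-fold (3.08 to 3.25) higher, with 94.8 kb of introns, Tnfaip3 was 3.08-fold (2.91 to 3.27) higher, and Nfkbia was 1.897-fold (1.85 to 1.95) lower. With TMM scaling, which moved the median of all genes from 0.0793 to -0.37, the NF-kB median was 0.24.

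The hillock and squamous list stood at 1.43 (1.41 to 1.44), at percentile 99.95 of the random lists, with Krt6a, a keratin of stressed epithelium, at 193 against 8.53 CPM and the aquaporin gene Aqp3 at 109 against 5.48 CPM. The mesenchymal list stood at 1.73 (1.65 to 1.802), at percentile 99.9 of the random lists, with Vim, the vimentin gene, 36.4-fold (29.2 to 46.03) and Fn1, the fibronectin gene, 9.42-fold (8.79 to 10.1) higher, but at -0.08 once the Krt4-high clusters were counted as basal-like. The YAP and TEAD target list was lower, at -1.12 (-1.32 to -0.92), at percentile 0.0400 of the random lists, with Cyr61 at 406 against 1644 CPM and Amotl2 at 24.7 against 82.02 CPM, while Tead1, with 214 kb of introns, was 2.92-fold (2.81 to 3.02) higher. The immediate early list stood at -0.71 (-0.74 to -0.68), at percentile 0.0800 of the random lists, with Nr4a1 4.19-fold (4.04 to 4.34) and Zfp36 3.24-fold (3.11 to 3.38) lower and Hspa1a, whose near-identical copy makes it uncertain, 7.26-fold (7.07 to 7.47) higher. Genes with under 3 kb of introns had a median of -0.45 in this comparison, with quartiles of -0.83 and 0.03. The random lists were not matched on intron length, so the percentiles in this comparison can reflect it. The Notch list stood at -0.58 (-0.64 to -0.53), at percentile 3.45 of the random lists, with the ligand genes Dll1 2.97-fold (2.59 to 3.41) and Jag2 2.85-fold (2.63 to 3.09) lower and Jag1 4.77-fold (4.53 to 5.03) higher, and at 0.16 without the minimum level for members. Krt8 and Krt18 were 1.497-fold (1.47 to 1.53) and 1.501-fold (1.48 to 1.53) higher. Krt5, Trp63, Ar and Pten were 1.501-fold (1.46 to 1.54), 1.48-fold (1.401 to 1.56), 1.71-fold (1.63 to 1.80) and 1.35-fold (1.25 to 1.46) lower. Krt5 has 3.63 kb of introns. Genes with 3 to 10 kb had log2 quartiles of -0.74 and 0.13 in this comparison, a range that holds the Krt5 ratio. Krt14 had a log2 ratio of 0.19 that was -0.23 with TMM scaling and -0.08 with the Krt4-high clusters counted as basal-like.

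Within the naming limits the highest ratios belonged to Ifi202b (ENSMUSG00000026535, chromosome 1, 173962568 to 173982744) at 1129 against 2.601 CPM, an interferon-inducible gene whose level is known to differ between mouse strains and which has close copies, and to 5 genes with 24.7 to 412 kb of introns. Tnc, the tenascin gene (79.5 kb of introns), was 424-fold (348 to 523) higher, Ngf, the nerve growth factor gene (49.6 kb), 1545-fold (813 to 3383), and Ldlrad4 (330.003 kb) 452-fold (329 to 640.3). Glis3 (412 kb) was 193-fold (167 to 224), and the hyaluronan synthase gene Has2 (24.7 kb) at least 2512-fold higher against 0 UMIs. The lowest were Ptp4a1 (114-fold (80.2 to 169.7) lower), the retinal dehydrogenase gene Aldh1a1 (13.3-fold (11.97 to 14.9)), the homeobox gene Hoxb13 (8.09-fold), Sbspon (7.88-fold), the transcription factor gene Srf (7.89-fold) and the lipid carrier gene Fabp5 (7.52-fold). Ngf, Glis3 and Ptp4a1 overlap a gene that only 1 of the feature tables lists, so their ratios are uncertain. In this comparison genes with at least 100 kb of introns had a median log2 ratio of 1.32 and genes with under 10 kb a median of -0.41. That is a gap of 1.73 (1.63 to 1.84), against -0.21 (-0.24 to -0.18) between 6 weeks and wild-type, where the software version is the same. The interferon members with under 10 kb of introns and no such overlap, 14 of 21, had a median of 1.90.

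**Figure D4:**
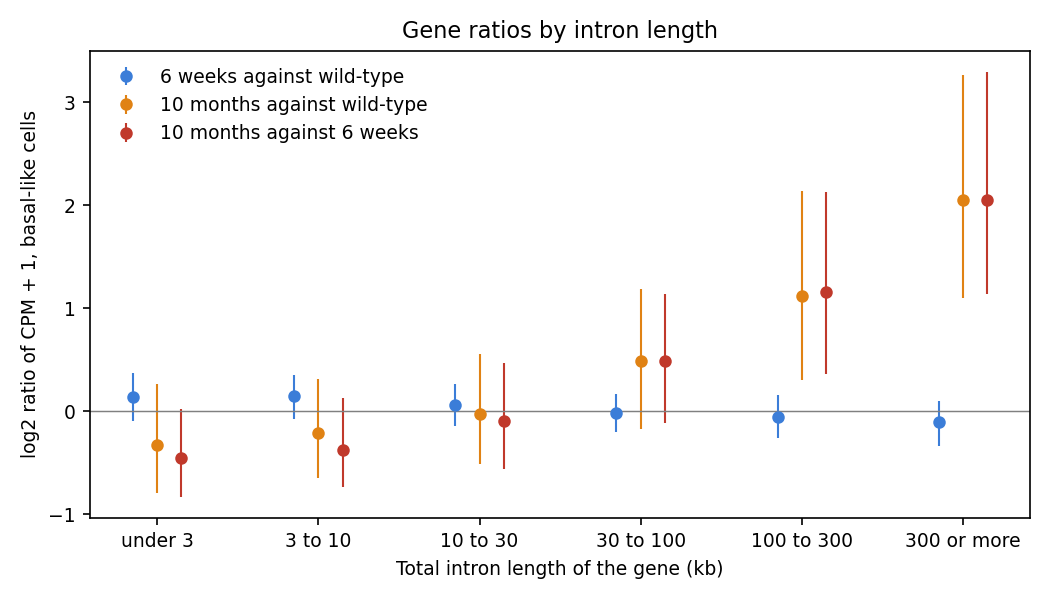
Median log2 ratio of genes (points) in bins of total intron length in kb, for basal-like cells, with bars over the middle 50% of genes. For 10 months against 6 weeks the median runs from -0.45 for genes with under 3 kb of introns to 2.05 for genes in the longest bin, while for 6 weeks against wild-type it runs from 0.14 to -0.10.

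Basal-like cells at 10 months, compared with wild-type, also carried higher levels of interferon genes, with a list median of 2.38 (2.29 to 2.54), above all 10000 random lists, and 18 of 21 measured members higher. The NF-kB list stood at 0.601 (0.49 to 0.69), at percentile 96.5 of the random lists, and at 0.18 with TMM scaling, which moved the median of all genes from 0.14 to -0.29. Nfkb1 was 2.81-fold (2.73 to 2.88) and Tnfaip3 2.68-fold (2.53 to 2.84) higher, and Nfkbia was 1.97-fold (1.92 to 2.02) lower. The long introns of Nfkb1 make its ratio uncertain. Krt8 was 1.63-fold (1.59 to 1.66) and Krt14 1.38-fold (1.36 to 1.397) higher. Ar and Pten were 1.55-fold (1.48 to 1.63) and 1.796-fold (1.67 to 1.94) lower. Krt18 had a log2 ratio of 0.27 that was -0.12 with TMM scaling. Krt5 had a log2 ratio of -0.33, against 0.06 with the Krt4-high clusters counted as basal-like, and Trp63 of -0.0990, against 0.001 when each library was clustered by itself.

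Within the naming limits the highest ratios were those of Ifi202b (1129 CPM against 2 UMIs, 27169-fold (7519.7 to 224360.3)), Tnc (4161-fold (2191 to 9102)), Ngf (12526-fold (2247 to 494912)), the neuropeptide gene Calcb (at least 2819.6-fold), Ldlrad4 (387-fold (284 to 543)) and the integrin gene Itga2 (211-fold (185 to 241), 91.9 kb of introns). The lowest were those of Grp (1 UMI at 10 months against 193 CPM), Ptp4a1 (111-fold lower), Spon2 (37.6-fold), Aldh1a1 (21.5-fold), Pdlim2 (13.8-fold) and Srf (9.74-fold). The wild-type cells lay in clusters 1 (82.03%) and 11 (17.4%) and the 10-month cells in cluster 17 (99.7%). Genes with at least 100 kb of introns stood 1.55 (1.45 to 1.66) above those with under 10 kb on the log2 scale.

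Luminal-like cells at 6 weeks, compared with wild-type, carried higher levels of interferon, chemokine and antimicrobial genes, also where the cells compared were of the proximal kind in both libraries. Among proximal cells (1047 at 6 weeks, 95 in wild-type) the interferon list had a median log2 ratio of 2.95 (2.71 to 3.38), above all 10000 random lists, with 27 of 27 measured members higher. Ifit3 was measured at 285 CPM against 2 UMIs (266-fold (73.6 to 2196)) and Ifi27l2a was 5.75-fold (4.23 to 8.03) higher. The innate defence list stood at 2.31 (2.22 to 3.03), above all 10000 random lists, with Ltf, the lactoferrin gene (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767), at 1101 against 9.104 CPM (121-fold (75.5 to 208)) and Reg3g at least 117-fold higher, while Lbp was 11.1-fold (10.2 to 12.1) lower. The chemokine list stood at 2.34 (2.26 to 2.77), above all 10000 random lists, with Ccl20, which draws CCR6-bearing lymphocytes, at 213 CPM against 1 UMI (398-fold (71.5 to 15741)) and Cxcl5 at least 98.9-fold higher against 0 UMIs.

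The NF-kB list stood at 1.91 (1.5001 to 2.13), above all 10000 random lists among proximal cells, with 21 of 24 measured members higher, of which Birc3 was 1.46-fold (1.18 to 1.82) and Tnfaip3 1.43-fold (1.25 to 1.64) higher. Nfkb1 did not differ beyond counting error (1.03-fold (0.906 to 1.18) lower) and Nfkbia was 1.14-fold (1.08 to 1.198) lower, but in the clustering with 297 wild-type proximal cells their log2 ratios were 1.29 and 1.80. There the interferon list stood at 3.97 and the NF-kB list at 2.80. The MHC class I list stood at 1.51 (1.32 to 1.64), above all 10000 random lists, with H2-K1 at 3053 against 832 CPM and Psmb8 4.92-fold (4.12 to 5.91) higher. The cell cycle list stood at 2.92 (2.45 to 3.38), above all 10000 random lists, with Ube2c 14.7-fold (6.74 to 40.2) and Birc5, at 2 UMIs in wild-type, 36.2-fold (10.01 to 299.6) higher, without the cycling cluster. It stood at 1.16 to 1.92 in the other clusterings. The sterol synthesis list stood at 1.41 (1.25 to 1.56), above all 10000 random lists, with Idi1 3.26-fold (2.61 to 4.13) and Hmgcs1 2.78-fold (2.32 to 3.36) higher. The glycolysis list stood at 1.12 (1.06 to 1.26), above all 10000 random lists, with Gapdh 3.15-fold (2.93 to 3.38) and Eno1 2.51-fold (2.18 to 2.91) higher. The p53 list stood at 1.06 (0.69 to 1.23), at percentile 99.96 of the random lists, with Plk2 3.73-fold (3.24 to 4.32) and the cyclin-dependent kinase inhibitor gene Cdkn1a 1.56-fold (1.39 to 1.77) higher.

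The proximal luminal list stood at only 0.25 (0.23 to 0.28), at percentile 89.97 of the random lists among proximal cells, and at 2.76 in the clustering with 297 wild-type proximal cells. Ly6a was 21.5-fold (18.2 to 25.6) and Ly6d 95.3-fold (58.7 to 167) higher, and Psca 7.41-fold (7.14 to 7.68) and Krt7 2.08-fold (1.93 to 2.24) lower. The androgen-responsive list stood at -0.42 (-0.58 to -0.0897), at percentile 0.0900 of the random lists, with Azgp1 7.02-fold (5.75 to 8.54) and Msmb 1.46-fold (1.37 to 1.56) lower and Aldh1a3 3.28-fold (2.14 to 5.32) higher. Wild-type proximal cells held Msmb at 574 CPM, within the 417 to 4705 CPM of wild-type macrophages and fibroblasts. At 6 weeks proximal cells held 393 CPM, and macrophages and fibroblasts 21.4 and 17.2 CPM. The lower secretory RNA at 6 weeks therefore cannot be given to the proximal cells. Krt8 and Krt18 were 1.38-fold (1.34 to 1.43) and 1.27-fold (1.22 to 1.31) higher. Krt14 was 1.47-fold (1.31 to 1.66) higher, Pten was 1.48-fold (1.28 to 1.699) lower, and Ar, Krt5 and Trp63 did not differ beyond counting error (1.06-fold, 1.002-fold and 1.01-fold).

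With distal and proximal cells together, 1207 luminal-like cells at 6 weeks and 1592 in wild-type, the medians also carry the different mix of both kinds. They were 3.82 (interferon), 2.595 (NF-kB), 2.67 (MHC class I), 3.02 (innate defence), 3.55 (chemokines), 2.42 (cell cycle), 1.72 (sterol synthesis), 1.85 (glycolysis), 1.41 (p53), 3.75 (proximal luminal) and -0.47 (androgen-responsive, but 0.16 with coarser clusters). The median of all genes was 0.51, and 0.05 with TMM scaling. Among distal cells alone the interferon median was 0.96 and the NF-kB median 1.16. Within the naming limits the highest ratios in the joint class were Ltf (1929-fold (1249 to 3158)), Wfdc18 (835-fold), YFP, Sprr2a3 (1482-fold, uncertain because of near-identical copies), Ly6d (285-fold) and Ccl20 (3727-fold (1031 to 30779)). The lowest were secreted products and surface proteins of the distal lobes, namely Ibsp (1 UMI at 6 weeks against 179.6 CPM), Msmb (46.02-fold), Cd59a (39.2-fold), Azgp1 (21.8-fold), Spink1 (20.4-fold) and the renin gene Ren1 (20.3-fold lower). Nfkb1, Nfkbia, Tnfaip3 and Ar were 2.73-fold, 3.95-fold, 12.7-fold and 2.11-fold higher in the joint class, so the direction for Nfkbia depends on the mix.

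Luminal-like cells at 10 months, compared with 6 weeks, carried MHC class II genes at far higher levels and cell cycle, sterol synthesis and secretory genes at lower levels. Cd74, the invariant chain of MHC class II (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), was 835 against 27.3 CPM, 30.6-fold (28.7 to 32.7) higher. H2-Ab1 was 40.1-fold (34.4 to 47.02) and H2-Aa 33.8-fold (28.8 to 39.8) higher, and the list of 5 measured members had a median log2 ratio of 4.796 (4.61 to 4.92), above all 10000 random lists. A Cd74 UMI was found in 41.6% (40.0 to 43.2) of luminal-like cells at 10 months and 3.23% (2.25 to 4.49) at 6 weeks after thinning to 2000 UMIs. It was found in 0 of 35 and 0 of 34 fibroblasts. Median depths before thinning were 20403, 28547, 4425 and 8177 UMIs. The innate defence list stood at 0.86 (0.798 to 0.92), at percentile 99.98 of the random lists, with the complement gene Cfb 14.6-fold (12.3 to 17.4) and Slpi 5.91-fold (5.63 to 6.19) higher and Saa3 4.12-fold (3.98 to 4.27) lower. Cfb overlaps a gene that only 1 feature table lists, which makes its ratio uncertain.

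The cell cycle list stood at -2.13 (-2.22 to -2.02), below all 10000 random lists, with Mki67 at 3.65 against 39.2 CPM and Cdk1 at 3.51 against 29.98 CPM, and 12 of 14 measured members at least 2-fold lower. The cycling cluster is outside this class, and with its cells put in the class of their larger keratin set the list stood at -2.29. The sterol and fatty acid list stood at -1.63 (-1.68 to -1.59), below all 10000 random lists, with Fasn, the fatty acid synthase gene, 5.36-fold (5.01 to 5.73) and Insig1 4.43-fold lower. The androgen-responsive list stood at -1.47 (-1.56 to -1.38), below all 10000 random lists, led by Sbp, the spermine-binding protein gene (ENSMUSG00000024128, chromosome 17, 23941672 to 23945607), at 1.03 CPM against 23991 CPM. The 10-month library held no distal secretory cells, and its 56 macrophages held no Sbp UMI, but held Svs2, a seminal vesicle gene, at 504 CPM. The 6-week class held 160 distal beside 1047 proximal cells, so part of the secretory difference may come from the mix. In 6-week proximal cells alone Spink1 was 950 CPM and Nkx3-1 22.2 CPM. These lie below their levels in the whole class but above the 0.011 and 0.158 CPM at 10 months.

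The NF-kB list stood at 0.44 (0.42 to 0.48), at percentile 99.2 of the random lists (-0.0538 among proximal cells of libraries clustered by themselves), and the interferon list at 0.35 (0.32 to 0.38), at percentile 97.1 of the random lists, both far closer to 0 than in the comparison of 6 weeks with wild-type. Tnfaip2 was 5.50-fold (4.96 to 6.11), Cxcl5 4.53-fold (4.398 to 4.66), Nfkb1 4.43-fold (4.29 to 4.57) and Tnfaip3 1.28-fold (1.24 to 1.32) higher, and Nfkbia was 1.22-fold (1.21 to 1.24) lower. The long introns of Nfkb1 make its ratio uncertain here as well. Genes with under 10 kb of introns had a median log2 ratio of -0.43 in this comparison, so the direction of small ratios is uncertain too. Among interferon genes Cxcl9 was 11.6-fold (9.21 to 14.7) and Ifi27l2a 2.32-fold (2.25 to 2.402) higher, and Cxcl10 1.704-fold (1.66 to 1.75) and Ifit2 2.27-fold (2.14 to 2.42) lower. The hillock and squamous list stood at 1.33 (1.23 to 1.38), at percentile 99.96 of the random lists, with Sfn 2.89-fold (2.84 to 2.94) and Krt16 2.71-fold (2.56 to 2.88) higher, but with coarser clusters the list stood at -0.28 and Krt16 at -0.03. The luminal identity list stood at -0.17 (-0.18 to -0.16), at percentile 43.2 of the random lists, with the prostate homeobox genes Nkx3-1 at 0.158 against 34.2 CPM and Hoxb13 at 47.6 against 290.1 CPM, while its members with short introns had a median of 0.09. Krt8 and Krt18 were 1.64-fold (1.63 to 1.65) and 1.55-fold (1.54 to 1.56) higher, and Krt5, Krt14, Trp63, Ar and Pten were 2.05-fold, 1.89-fold, 3.30-fold, 1.38-fold and 1.26-fold lower.

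Within the naming limits the highest ratios were those of Reg1 (264 CPM against 0 UMIs, at least 3037-fold), Atp6v0c (207-fold (163 to 267)), Glis3 (189.7-fold (147 to 249), 412 kb of introns), eGFP (at least 1279-fold), Rnasek (162-fold (121 to 223)) and Thsd4 (182-fold (117 to 303), 541 kb of introns). Atp6v0c, a proton pump subunit gene with processed copies, and Rnasek, which overlaps a gene of 1 table, were near 0 in both libraries of the older software version, so neither ratio can be read as expression. The same holds for the reporter sequence eGFP, with 0 UMIs at 6 weeks in a library that held YFP. The lowest were Sbp (23337-fold (19007 to 28985) lower), the defensin gene Defb50 (32568-fold (16528 to 75439)), Spink1 (1 UMI at 10 months against 2262 CPM), Sbpl (12606-fold), the probasin gene Pbsn (1 UMI against 825 CPM) and Msmb (at least 21106-fold lower against 0 UMIs). Only the 6-week class held distal cells, which can add to these ratios. The median of all genes was -0.102, and genes with at least 100 kb of introns stood 1.49 (1.43 to 1.59) above those with under 10 kb. The 6-week cells lay mostly in cluster 14 (74.8%) and the 10-month cells in clusters 22 (69.9%) and 18 (30.01%).

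**Figure D5:**
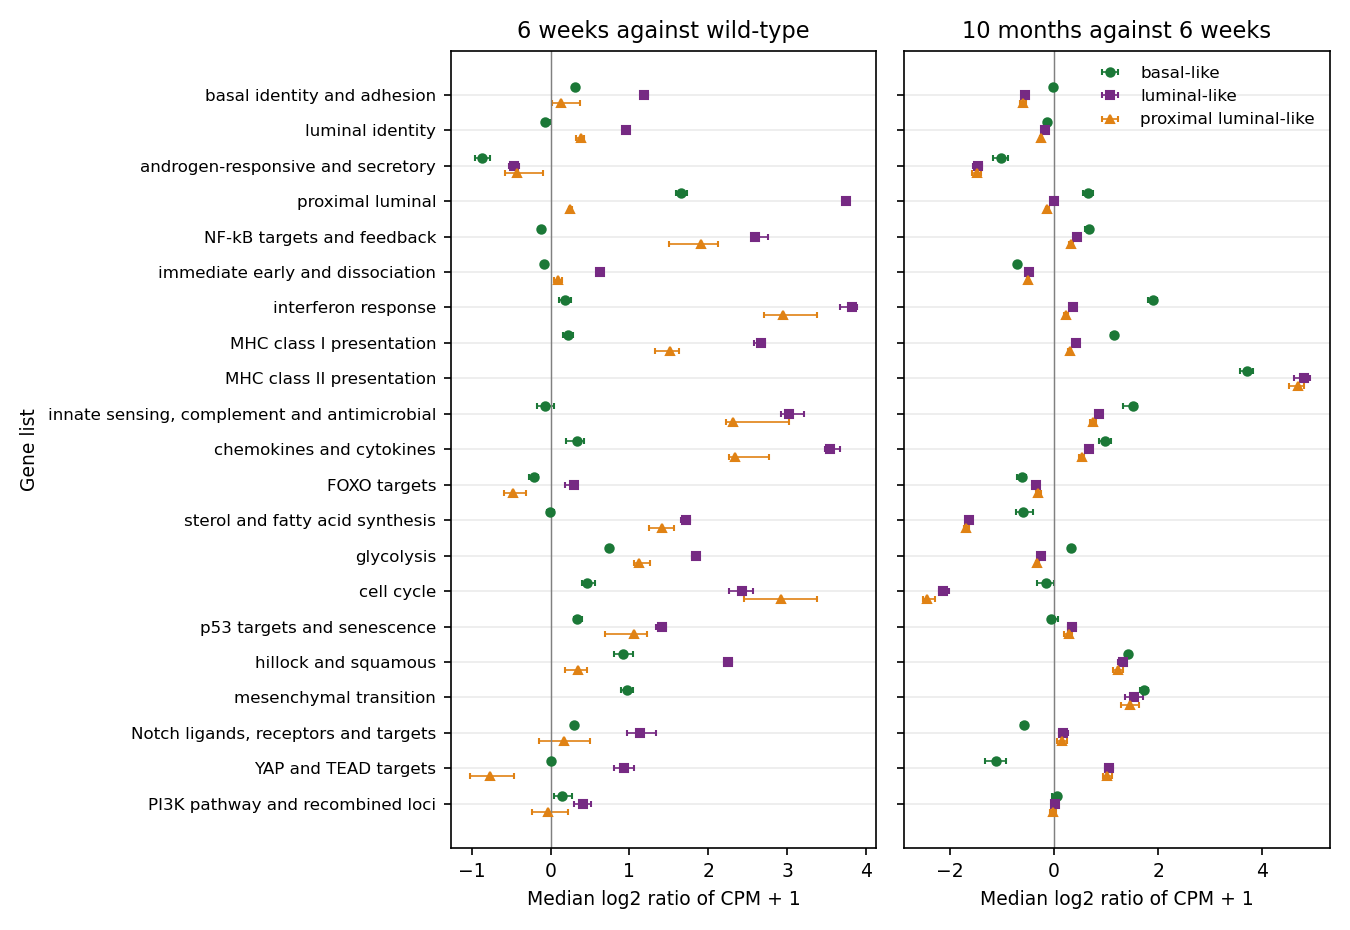
Median log2 ratio of the gene lists (points) in basal-like, luminal-like and proximal luminal-like cells, for 6 weeks against wild-type (left) and 10 months against 6 weeks (right), with 95% intervals from 1000 Poisson redraws as bars, which cover counting error only. In basal-like cells the interferon list stands at 0.18 (left) and 1.91 (right), and in luminal-like cells at 3.82 and 0.35.

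Luminal-like cells at 10 months, compared with wild-type, likewise carried higher levels of interferon and NF-kB genes. Among proximal cells (3652 at 10 months, 95 in wild-type) the interferon list had a median log2 ratio of 3.54 (3.199 to 3.73), above all 10000 random lists, and the NF-kB list one of 2.03 (1.899 to 2.44), above all 10000 random lists. Ltf was 1609.8 against 9.104 CPM (177-fold (110.4 to 304)). Cxcl5 and Reg3g were at least 404-fold and at least 395-fold higher against 0 UMIs. Ly6d was 180.2-fold (111 to 315) and Wfdc18 43.5-fold (32.5 to 59.6) higher, and Ifi202b was 649.7 CPM against 2 UMIs. The proximal genes Psca and Krt7 were 23.7-fold (22.8 to 24.6) and 1.897-fold (1.77 to 2.04) lower. Nfkb1 was 4.11-fold (3.62 to 4.68) and Tnfaip3 1.66-fold (1.46 to 1.91) higher, and Nfkbia 1.48-fold (1.41 to 1.55) lower. The Nfkb1 ratio is uncertain here too, because of its long introns. In the clustering with 297 wild-type proximal cells Nfkbia, Krt7, Krt5 and Ar had log2 ratios of 1.41, 1.41, 0.10 and 0.0942, the other direction. Krt8 and Krt18 were 2.14-fold (2.06 to 2.21) and 1.901-fold (1.84 to 1.97) higher, and Krt5, Trp63, Ar and Pten were 1.93-fold, 3.15-fold, 1.35-fold and 1.89-fold lower. The secretory genes Sbp, Spink1, Msmb, Defb50, Sbpl and Pbsn were 5341, 3295, 574, 4195, 918 and 431 CPM in wild-type proximal cells, where free RNA adds to them, and at most 1.03 CPM at 10 months. Of the wild-type proximal cells 98.9% lay in cluster 14, and the 10-month cells lay in clusters 22 (69.9%) and 18 (30.01%), so the classes compared share almost no cluster.

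With distal cells included, the wild-type class held 1592 cells, the interferon list stood at 3.94 (3.84 to 4.06), above all 10000 random lists, and the NF-kB list at 3.604 (3.55 to 3.66), above all 10000 random lists. The median of all genes was 0.48, and 0.02 with TMM scaling. In this joint class Nfkbia and Ar were 3.22-fold and 1.54-fold higher, the reverse of the proximal cells, and Krt14 was 1.23-fold (1.19 to 1.28) higher but had a log2 ratio of -0.12 with TMM scaling. The same 6 secretory genes had the lowest ratios within the naming limits, and Ltf (3111-fold (2014 to 5093)), Cxcl5, Reg3g, Ifi202b, Ly6d and Wfdc18 the highest.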

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

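The tests of immune cell RNA, of YFP-negative cells and of shallow clusters were chosen after their results had been seen, and the tests of introns, gene models and short-intron interferon genes were chosen before.

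Some genes went in opposite directions in basal-like and luminal-like cells, or at 6 weeks and 10 months, against the same library, and none of these differences between classes or time points was tested. Relative to wild-type on the log2 scale, the NF-kB list stood at -0.12 in basal-like and 2.60 in luminal-like cells at 6 weeks, and at 0.60 in basal-like cells at 10 months. Nfkbia stood at -0.0533 and 1.97 at 6 weeks and at -0.98 and 1.68 at 10 months, and Birc3 at -0.63 and 1.25 at 6 weeks, basal-like first. Nfkb1 stood at -0.17 and 1.43 at 6 weeks and at 1.48 in basal-like cells at 10 months, where its long introns make the value uncertain. Tnfaip3 stood at -0.20 and 3.56 at 6 weeks and at 1.41 in basal-like cells at 10 months. Ar stood at 0.14 in basal-like cells at 6 weeks and at -0.63 at 10 months, where luminal-like cells stood at 0.61. Krt18 stood at -0.32 in basal-like and 0.85 in luminal-like cells at 6 weeks and at 0.27 in basal-like cells at 10 months. Krt5 stood at 0.26 and -0.33 in basal-like cells at 6 weeks and 10 months. Trp63 stood at 0.46 and -0.10 in basal-like and at 0.76 and -0.76 in luminal-like cells at the same times. Krt14 at 10 months against 6 weeks stood at 0.19 in basal-like and -0.92 in luminal-like cells. The basal-like sign of several turned under alternatives, so opposite directions that rest on these signs are lost there. Krt14 at 10 months against 6 weeks stood at -0.23 with TMM scaling and at -0.0793 with Krt4-high clusters counted as basal-like, where Krt5 at 10 months stood at 0.0569. Krt18 at 10 months stood at -0.12 with TMM scaling, and Trp63 at 0.00100 with each library clustered by itself. The luminal-like values mix distal and proximal cells in the wild-type library, and among proximal cells alone Nfkbia stood at -0.19 and -0.56, Nfkb1 at -0.0490 at 6 weeks and Ar at -0.43 at 10 months. Among the same cells Trp63 stood at -0.0190 and -1.46, and at 6 weeks Tnfaip3 stood at 0.51, Birc3 at 0.53 and Krt18 at 0.34. These values depend on the clustering: with 297 instead of 95 wild-type proximal cells Nfkbia stood at 1.80 and 1.41, Nfkb1 at 1.29 and Trp63 at 1.03 at 6 weeks.

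Signals outside the comparisons also stood out. At 10 months the reporter and Cre sequences of the gene table gave 99.3 CPM for eGFP, 12.5 CPM for mCherry, which only that table lists, and 0.642 CPM for CRE, while eGFP and CRE had 0 UMIs in the other libraries. Neuroendocrine-like cells made up 0.413% (0.277 to 0.593) of the 10-month library, and small clusters without a class 0.897% (0.690 to 1.15).

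Genes with long introns, and a set of other genes, stood far higher at 10 months than at 6 weeks, in a table made by another software version. The gap between genes with at least 100 kb and under 10 kb of introns was 1.73 (1.63 to 1.84) on the log2 scale in basal-like cells, against -0.21 between libraries made with the same version, which is consistent with intronic reads being counted in the 10-month library only. Of 140 genes at least 8-fold higher in both classes 19 lay over a gene that only the older table lists, a share 5.70 (3.52 to 8.56) times that of all genes, so different gene models may account for part of them. These tests do not separate processing from time after deletion gene by gene. A change in transcription of long genes during tumour growth stays open and untested.

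Interferon genes in basal-like cells and MHC class II genes in luminal-like cells were higher at 10 months than at 6 weeks. For the interferon genes the tables argue against intronic reads and overlapping gene models. Members with under 10 kb of introns and no overlap had a median log2 ratio of 1.90 (1.75 to 1.95) against 1.91 for the whole list. That test does not cover other differences between the references. Atp6v0c, with 2.45 kb of introns and no overlap with a gene of the older table only, stood at 353 against 1.67 CPM in basal-like cells. The tables also argue against RNA of the 56 immune cells: the gain of the interferon genes was 114.3 (80.9 to 144) times what the immune markers allow, and Cd74 stood 64.9 times above its allowed level of 12.9 CPM. Strain, age, the pooling of few mice, free RNA of other epithelial cells and other differences in processing stay open, and no test separates them. As a gauge of free RNA, fibroblasts of the 10-month library held Cd74 at 20.9 CPM (7.66 to 45.4), against 835 CPM in luminal-like cells. Free RNA of the other MHC class II genes and of the interferon genes other than Cxcl10 was not gauged in this way. A response of Pten-deleted epithelium to inflammation may underlie the pattern, an untested hypothesis that replicate littermates with and without the interferon receptors in traced cells would decide.

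Luminal-like cells made up a larger share of the YFP-sorted library at 10 months than at 6 weeks. Unmarked luminal cells passing the sort could produce this, but 37.9% (36.3 to 39.5) of luminal-like cells had a reporter UMI after thinning, above the midpoint of 21.8% between non-epithelial and basal-like cells. That test was made at 10 months only. At 6 weeks 30.6% (22.9 to 39.1) of the distal luminal-like cells had a reporter UMI. Leaving out shallow cells could also shift the share, but with shallow clusters named by their keratins the share was 3.05 times that at 6 weeks. A share of unmarked cells below that midpoint, loss of basal cells during dissociation and the differing mice stay open. Passage of traced basal cells to a luminal state, or faster growth of luminal cells that were marked early, are biological explanations that these libraries do not separate, and neither was tested.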

How the results depend on the processing

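How the results depend on the processing was checked by running each alternative once, and the cause of no difference was tested. Of the values under alternatives, 897 of single genes stayed inside the interval of the report, 1511 left it with the same sign and 9 turned sign. For list medians these counts were 311, 388 and 8. Of the cell shares 31 stayed and 31 moved, of the keratin shares 13 and 10, and of the shares with both keratin sets 8 and 16. The intervals cover counting error only and are narrow at this depth, so small differences leave them. With coarser clusters 8 basal-like cells were left at 10 months, so that setting has no 10-month keratin, list or gene value for this class. The removal of the highest doublet scores, the counting of Krt4-high clusters as basal-like, the naming of shallow clusters, the restriction to short introns, the adding of cycling cells and proximal cells as named in other clusterings were chosen after the data had been seen. Free RNA and the depth of each cell limit every share of cells with a UMI. Ratios name the first library over the second.

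With at least 1000 genes per cell, shares of cells were basal-like wild-type 68.1%, basal-like 6 weeks 63.7%, luminal-like 6 weeks 15.6%. With at most 10% mitochondrial UMIs, shares of cells were basal-like wild-type 67.2%, basal-like 6 weeks 65.2%, luminal-like wild-type 17.99%. Epithelial cells with both keratin sets were wild-type 58.1%, 6 weeks 72.8%, 10 months 54.2%. NF-kB luminal-like 2.78 (log2, 6 weeks/wild-type). NF-kB luminal-like 3.71 (log2, 10 months/wild-type). NF-kB luminal-like 0.52, interferon luminal-like 0.38 (log2, 10 months/6 weeks). With shallow clusters named by their keratins, shares of cells were basal-like wild-type 70.1%, basal-like 6 weeks 67.6%, luminal-like wild-type 26.2%. With class by the larger keratin set per cell, shares of cells were basal-like wild-type 65.7%, basal-like 6 weeks 80.1%, basal-like 10 months 36.2%, luminal-like wild-type 27.8%, luminal-like 10 months 61.3%. With coarser clusters, shares of cells were basal-like 6 weeks 69.2%, basal-like 10 months 0.114%, luminal-like wild-type 15.8%, luminal-like 6 weeks 19.4%, luminal-like 10 months 54.01%. Luminal keratin shares of basal-like cells were 6 weeks 14.8%. NF-kB basal-like -0.0692, interferon basal-like 0.61, androgen-responsive and secretory luminal-like 0.16 (sign turned), NF-kB luminal-like 2.48, interferon luminal-like 3.63 (log2, 6 weeks/wild-type). NF-kB luminal-like 3.499 (log2, 10 months/wild-type). NF-kB luminal-like 0.59, interferon luminal-like 0.38, hillock and squamous luminal-like -0.28 (sign turned), Krt16 luminal-like -0.0339 (sign turned) (log2, 10 months/6 weeks). With each library clustered by itself, shares of cells were basal-like 6 weeks 68.5%, basal-like 10 months 25.3%, luminal-like wild-type 15.4%, luminal-like 6 weeks 13.7%, luminal-like 10 months 49.95%. Luminal keratin shares of basal-like cells were 6 weeks 14.8%. NF-kB basal-like -0.0735, interferon basal-like 0.57, NF-kB luminal-like 2.92, interferon luminal-like 3.94 (log2, 6 weeks/wild-type). NF-kB basal-like 0.87, interferon basal-like 2.58, Trp63 basal-like 0.00100 (sign turned), NF-kB luminal-like 3.86 (log2, 10 months/wild-type). NF-kB basal-like 0.89, interferon basal-like 1.605, interferon luminal-like 0.395 (log2, 10 months/6 weeks). With doublets kept, shares of cells were luminal-like wild-type 13.7%, luminal-like 6 weeks 15.6%. Luminal keratin shares of basal-like cells were 6 weeks 14.3%, 10 months 34.1%. NF-kB luminal-like 2.8001, interferon luminal-like 4.01 (log2, 6 weeks/wild-type). Interferon basal-like 2.74, NF-kB luminal-like 3.77 (log2, 10 months/wild-type). Interferon basal-like 2.23, interferon luminal-like 0.28 (log2, 10 months/6 weeks). With Krt8 and Krt18 against Krt5 and Krt14 only, luminal keratin shares of basal-like cells were wild-type 36.2%, 6 weeks 29.6%, 10 months 38.2%. With Krt4-high clusters counted as basal-like, luminal keratin shares of basal-like cells were 6 weeks 17.3%, 10 months 32.8%. NF-kB basal-like -0.0459, interferon basal-like 1.15 (log2, 6 weeks/wild-type). NF-kB basal-like 0.83, interferon basal-like 3.13, Krt5 basal-like 0.0569 (sign turned) (log2, 10 months/wild-type). NF-kB basal-like 0.78, interferon basal-like 1.704, mesenchymal transition basal-like -0.0756 (sign turned), Krt14 basal-like -0.0793 (sign turned) (log2, 10 months/6 weeks). With the highest doublet scores removed, luminal keratin shares of basal-like cells were 10 months 27.8%. Epithelial cells with both keratin sets were 10 months 49.7%. Interferon basal-like 0.0682, NF-kB luminal-like 2.92, interferon luminal-like 3.92 (log2, 6 weeks/wild-type). NF-kB luminal-like 3.905 (log2, 10 months/wild-type). NF-kB basal-like 0.55, NF-kB luminal-like 0.49 (log2, 10 months/6 weeks). With thinning to 1000 UMIs, epithelial cells with both keratin sets were wild-type 27.5%, 6 weeks 46.3%, 10 months 33.04%. With no thinning, epithelial cells with both keratin sets were wild-type 75.2%, 6 weeks 93.8%, 10 months 80.4%. With at least 1 UMI of each keratin set, epithelial cells with both keratin sets were wild-type 73.95%, 6 weeks 86.01%, 10 months 67.8%. With at least 3 UMIs of each keratin set, epithelial cells with both keratin sets were wild-type 38.02%, 6 weeks 55.6%, 10 months 40.6%. With the total without the 50 top genes, NF-kB basal-like -0.17, interferon basal-like 0.44, NF-kB luminal-like 2.399, interferon luminal-like 3.45 (log2, 6 weeks/wild-type). NF-kB basal-like 0.43, NF-kB luminal-like 3.14, interferon luminal-like 3.51, Krt14 luminal-like -0.17 (sign turned) (log2, 10 months/wild-type). NF-kB basal-like 0.52, interferon basal-like 1.78, NF-kB luminal-like 0.37, interferon luminal-like 0.29 (log2, 10 months/6 weeks). With cycling cells added by their larger keratin set, NF-kB basal-like -0.16, interferon basal-like 0.38 (log2, 6 weeks/wild-type). Interferon basal-like 2.73 (log2, 10 months/wild-type). With no minimum for members, NF-kB basal-like -0.17, interferon basal-like 0.504, chemokines and cytokines basal-like -0.0209 (sign turned), interferon luminal-like 3.52 (log2, 6 weeks/wild-type). NF-kB basal-like 0.45, NF-kB luminal-like 3.45 (log2, 10 months/wild-type). Interferon basal-like 1.77, Notch ligands basal-like 0.16 (sign turned), NF-kB luminal-like 0.35 (log2, 10 months/6 weeks). With members with short introns, NF-kB basal-like -0.0864, NF-kB luminal-like 3.54 (log2, 6 weeks/wild-type). NF-kB luminal-like 4.15, interferon luminal-like 4.301 (log2, 10 months/wild-type). Luminal identity luminal-like 0.0939 (sign turned), NF-kB luminal-like 0.52 (log2, 10 months/6 weeks). With TMM factors, NF-kB luminal-like 2.304, interferon luminal-like 3.38 (log2, 6 weeks/wild-type). NF-kB basal-like 0.18, interferon basal-like 2.02, Krt18 basal-like -0.12 (sign turned), NF-kB luminal-like 3.19, interferon luminal-like 3.54, Krt14 luminal-like -0.12 (sign turned) (log2, 10 months/wild-type). NF-kB basal-like 0.24, interferon basal-like 1.51, Krt14 basal-like -0.23 (sign turned), NF-kB luminal-like 0.56, interferon luminal-like 0.38 (log2, 10 months/6 weeks). With the mean of per-cell CPM, NF-kB luminal-like 2.35, interferon luminal-like 3.65 (log2, 6 weeks/wild-type). NF-kB basal-like 0.72, interferon basal-like 2.22, NF-kB luminal-like 3.03, interferon luminal-like 3.802, Krt14 luminal-like -0.68 (sign turned) (log2, 10 months/wild-type). Interferon basal-like 1.73, NF-kB luminal-like 0.503, interferon luminal-like 0.25 (log2, 10 months/6 weeks). With a pseudocount of 10 CPM, NF-kB luminal-like 1.91, interferon luminal-like 2.39 (log2, 6 weeks/wild-type). NF-kB basal-like 0.45, interferon basal-like 1.47, NF-kB luminal-like 2.61, interferon luminal-like 2.57 (log2, 10 months/wild-type). NF-kB basal-like 0.56, interferon basal-like 1.198, NF-kB luminal-like 0.39, interferon luminal-like 0.31 (log2, 10 months/6 weeks). With distal luminal-like cells only, NF-kB luminal-like 1.16, interferon luminal-like 0.96 (log2, 6 weeks/wild-type). With proximal luminal-like cells only, NF-kB luminal-like 1.91, interferon luminal-like 2.95 (log2, 6 weeks/wild-type). NF-kB luminal-like 2.03, interferon luminal-like 3.54 (log2, 10 months/wild-type). NF-kB luminal-like 0.31, interferon luminal-like 0.23 (log2, 10 months/6 weeks). With proximal luminal-like cells only, doublets kept, NF-kB luminal-like 2.804, interferon luminal-like 3.97 (log2, 6 weeks/wild-type). NF-kB luminal-like 3.36 (log2, 10 months/wild-type). NF-kB luminal-like 0.302, interferon luminal-like 0.16 (log2, 10 months/6 weeks). With proximal luminal-like cells only, clustering at resolution 0.4, NF-kB luminal-like 1.68, interferon luminal-like 2.84 (log2, 6 weeks/wild-type). NF-kB luminal-like 2.02, interferon luminal-like 3.57 (log2, 10 months/wild-type). NF-kB luminal-like 0.49, interferon luminal-like 0.29, hillock and squamous luminal-like -0.35 (sign turned) (log2, 10 months/6 weeks). With proximal luminal-like cells only, each library clustered by itself, NF-kB luminal-like 1.88, interferon luminal-like 3.26 (log2, 6 weeks/wild-type). NF-kB luminal-like 1.696, interferon luminal-like 3.57 (log2, 10 months/wild-type). NF-kB luminal-like -0.0538 (sign turned), interferon luminal-like 0.0754 (log2, 10 months/6 weeks).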

Other observations

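No test in this part was planned, and all values here describe cells chosen after they had been seen.

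The Krt4-high cells, kept out of the basal-like class, lay in different clusters at each time, as did most basal-like and luminal-like cells. The clustering had no batch integration, so library and processing cannot be told apart from a difference between the cells. The 6-week Krt4-high cells lay in cluster 3 (822 of 823) and the 10-month ones in cluster 20 (1811 of 1831). Between them the interferon list had a median log2 ratio of 0.72 (0.64 to 0.82), at percentile 99.9 of the random lists, and the NF-kB list one of 0.77 (0.69 to 0.82), at percentile 99.9 of the random lists, both higher at 10 months. Nfkb1, with 94.8 kb of introns, was at 677 CPM at 10 months and 184 CPM at 6 weeks in these clusters, and the chemokine gene Cxcl5, with short introns, at 618 CPM and 59.0 CPM. Other members were lower at 10 months, among them Nfkbia (1.32-fold), Rel (1.55-fold) and Lcn2 (1.705-fold) of the NF-kB list and Cxcl10 (4.49-fold) and Cxcl9 (2.87-fold) of the interferon list. A reporter UMI was found in 57.1% (53.6 to 60.5) of the 6-week and 27.9% (25.9 to 30.04) of the 10-month cells after thinning to 2000 UMIs. The shares at 10 months and 6 weeks were 31.0% and 55.3% in basal-like cells and 37.9% and 54.8% in luminal-like cells. The 10-month library was counted with another gene table, so none of these shares can be compared between the times.

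Rare cells were found mostly at 10 months. Neuroendocrine-like cells, 29 at 10 months and 1 in each other library, carried Chga at 2363 CPM, Calca at 7191 CPM and Ascl1 at 463 CPM, and 6 of the 29 had a reporter UMI after thinning (20.7%, 7.99 to 39.7), against 12.6% of non-epithelial cells. They held YFP at 149.9 CPM (124.01 to 179.7) and eGFP at 79.5 CPM (60.9 to 101.9), against 44.6 (32.7 to 59.5) and 38.8 (27.7 to 52.8) in non-epithelial cells. Cluster 16, with 37 cells at 10 months (0.527%), 4 at 6 weeks and 6 in wild-type, carried Foxi1, a regulator of ionocytes, at 301 CPM, Coch at 1563 CPM and Iapp at 10873 CPM. Cluster 21, with 26 cells (0.370%) at 10 months and 0 of 7149 and 0 of 8012 cells elsewhere, carried the urothelial genes Upk3a at 670.3 CPM and Krt20 at 354 CPM. These genes led their clusters, so their levels describe the cells and compare no groups.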
